A study of Mus musculus with 3 samples.

How the data were processed

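BCL11A is a zinc-finger transcription factor that silences globin genes of earlier developmental stages in red cell precursors. Its chromatin occupancy was measured in MEL cells, a mouse erythroleukemia line that resembles early red cell precursors. The cells expressed BCL11A with a FLAG and biotin tag together with BirA, the bacterial biotin ligase that biotinylates the tag, so that bound chromatin was captured on streptavidin beads and no antibody was needed. Per the labels' protocols, cells were kept in medium with 10% serum and fixed in 1% formaldehyde for 5 min, and 3 to 9 ng of captured DNA went into poly(A) tailing for single-molecule sequencing on the HeliScope. The labels name 3 samples, 1 each of tagged BCL11A, cells with BirA alone and input DNA, with no replicates. The peak list of the tagged BCL11A sample was analysed here. Peak lists or reads of the other 2 samples were not used here, so no comparison between samples was made, and no test below compares BCL11A with a control.

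The authors deposited peak intervals, each with 1 score. Per the file header, the peaks were called with CisGenome, and per the submitters' processing notes the genome build is mm9. The track name in the header reads "Bcl11a_XL_onES_pcut5 only". The meaning of "onES", "pcut5" and "only" is not given in the sources used here, so it is open which control the peaks were called against and whether the list is a subset of a longer one. The aligner, the caller's settings and the read depth are not given in the sources used here either. The deposited score has no stated scale. Its lowest value was 50, so a floor was applied, and it was used only to describe and rank peaks within this list. The list gives no read counts, so no interval that depends on read depth could be given. Peak names were numbered from 1 to 2370 without a gap, no interval was duplicated and no neighbouring peaks overlapped. All peak ends lay within the mm9 chromosome lengths. Intervals are printed counting from 1.

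Peak positions were taken at the centre of each interval, and the 21 chromosomes 1 to 19, X and Y were used, with mm9 lengths. Peaks per chromosome were compared with a uniform density by an exact two-sided binomial test with Benjamini-Hochberg adjustment over the 21 chromosomes. Spacing was compared with 1000 shuffles of the peaks within their chromosome (two-sided permutation p, smallest possible 0.002). Scores of peaks with and without a neighbour within 10 kb were compared by a two-sided permutation test of the medians with 100000 resamples (smallest possible p 2e-05), and rank correlation was tested with as many permutations. Intervals of medians and of their differences are 95% percentile bootstraps over peaks, and intervals of shares are 95% Wilson intervals. Peaks lie in clusters and are not independent, so these intervals and p-values describe this list and are too narrow as statements about cells. Shuffled positions were allowed in assembly gaps and in unmappable sequence. These tests, the 100 kb windows and the peaks named by rank (the 10 highest scores and the 5 densest windows) were set before the data were examined. Peak-dense domains were defined after seeing the data, as runs of at least 20 peaks whose neighbouring centres lie at most 250 kb apart.

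The gene table at hand belongs to assembly GRCm38.p6, not mm9, so it was used only to look up which chromosome carries a gene. The planned comparisons of peaks with transcription start sites, genomic classes, gene lists, named loci, motifs and base composition need mm9 annotation or sequence and were not run, and no peak is assigned to a gene. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The tests of spacing, chromosome counts, score differences and rank correlation, the domain rule and the merging of peaks were tested on simulated lists of 2370 peaks. Of 50 lists with uniform positions, 0 gave a spacing p below 0.05, 0 held a domain and 1 had a called chromosome. In 20 lists with 10 planted domains, the spacing test passed in 20 and exactly 10 domains were found in 20. Each planted domain had its own chromosome, so neighbouring domains were not simulated. The 200 extra peaks on chromosome 9 were called in 20 of 20 lists. A score shift of 5 was found in 50 of 50 lists, and 5 of 50 lists without a shift were called at p below 0.05 as well.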

Results

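The occupancy list of tagged BCL11A in MEL cells held 2370 peaks on 20 chromosomes, with none on chromosome Y. Together they covered 2.18 Mb, or 0.0821% of the mm9 chromosomes. The median width was 764 bp (95% interval 753 to 782), with quartiles at 675 and 1057 bp and a range of 216 to 3488 bp. The authors' score had a median of 59.4 (95% interval 58.8 to 60.2) and ran from 50 to 362.90. Most peaks lay close to the floor, since 1226 of 2370 (51.7%, Wilson interval 49.7 to 53.7) scored under 60, and 238 peaks (10.0%, 8.90 to 11.3) scored over 100. There is 1 library behind the list and no replicate, so no value below has an error between samples.

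Where BCL11A peaks lie along the genome was asked first. They were not spread by chromosome length. No control coverage was used, so in the counts below a regional gain in read coverage cannot be told apart from denser occupancy. Chromosome 9 alone held 1105 of the 2370 peaks (46.6%, Wilson interval 44.6 to 48.6), 9.98 times the 111 that a uniform density gives. Chromosome 3 held 320 peaks (2.25 times the uniform count), chromosome 8 held 208 (1.77 times), chromosome 19 held 113 (2.06 times), and chromosomes 12 and 15 held 145 each (1.34 and 1.57 times). These 6 chromosomes, with 2036 peaks, passed the exact binomial test as above the uniform count, the least firmly chromosome 12 (Benjamini-Hochberg adjusted p = 0.000585). Among the 1185 highest-scoring peaks, chromosomes 12 (1.09 times, exact test, adjusted p = 0.511) and 15 (0.93 times, exact test, adjusted p = 0.707) lost this call. Another 14 chromosomes passed it as below, with 241 peaks among them, and chromosome 14 with 93 peaks did not pass (0.83 times, exact test, adjusted p = 0.0728). With peaks within 10 kb merged, chromosome 14 was below as well (0.53 times, exact test, adjusted p = 0.000103), so that 6 chromosomes were above and 15 below. Without chromosome 9, chromosome 14 was instead above the uniform count of the remaining list (1.49 times, exact test, adjusted p = 0.000229), together with chromosomes 3, 8, 12, 15 and 19, and 14 chromosomes were below.

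The chromosomes that carry the globin genes held few peaks, as did others without a domain of dense peaks. Chromosome 7 carries the beta-like globin genes Hbb-bt, Hbb-bs and Hbb-y, which encode the beta-type chains of hemoglobin, and Sox6, a transcription factor that acts in globin silencing. It held 11 peaks, 0.0808 times the uniform count (adjusted p = 2.15e-44, exact binomial test). Leaving out the peaks in the dense domains described next, which raise the uniform count, the ratio was 0.326 (exact test, adjusted p = 1.92e-05). Chromosome 11 carries the alpha-globin genes Hba-a1 and Hba-a2 and Bcl11a itself, and held 10 peaks (0.0919 times, exact test, adjusted p = 2.27e-34; 0.371 times and adjusted p = 0.000395 without the domain peaks). Chromosomes 2, 10, 13, 16 and 18 had ratios of 0.0570 to 0.102 over all peaks, so the low count was not particular to the globin chromosomes. The median scores were 56.4 on chromosome 7 and 54.6 on chromosome 11, against 55.0 for all peaks outside the domains. The highest was 66.67 on chromosome 7, at 97104607 to 97105056, and 62.82 on chromosome 11, at 79483851 to 79484342. Chromosome 10, with Myb, a regulator of blood progenitors, and Zbtb7a, another silencer of globin genes of earlier stages, held 11 peaks. Chromosomes 4 (Tal1) and 6 (Gata2), which carry blood stem cell transcription factors, held 18 and 19, and chromosome X, with the erythroid master regulator Gata1, held 31. Klf1, an activator of adult beta-globin, and Zfpm1, a cofactor of Gata1, are on chromosome 8, where 201 of 208 peaks lay in the distal domains. These counts are per chromosome, and whether any of these peaks lies at one of the genes was not analysed here.

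**Figure D1:**
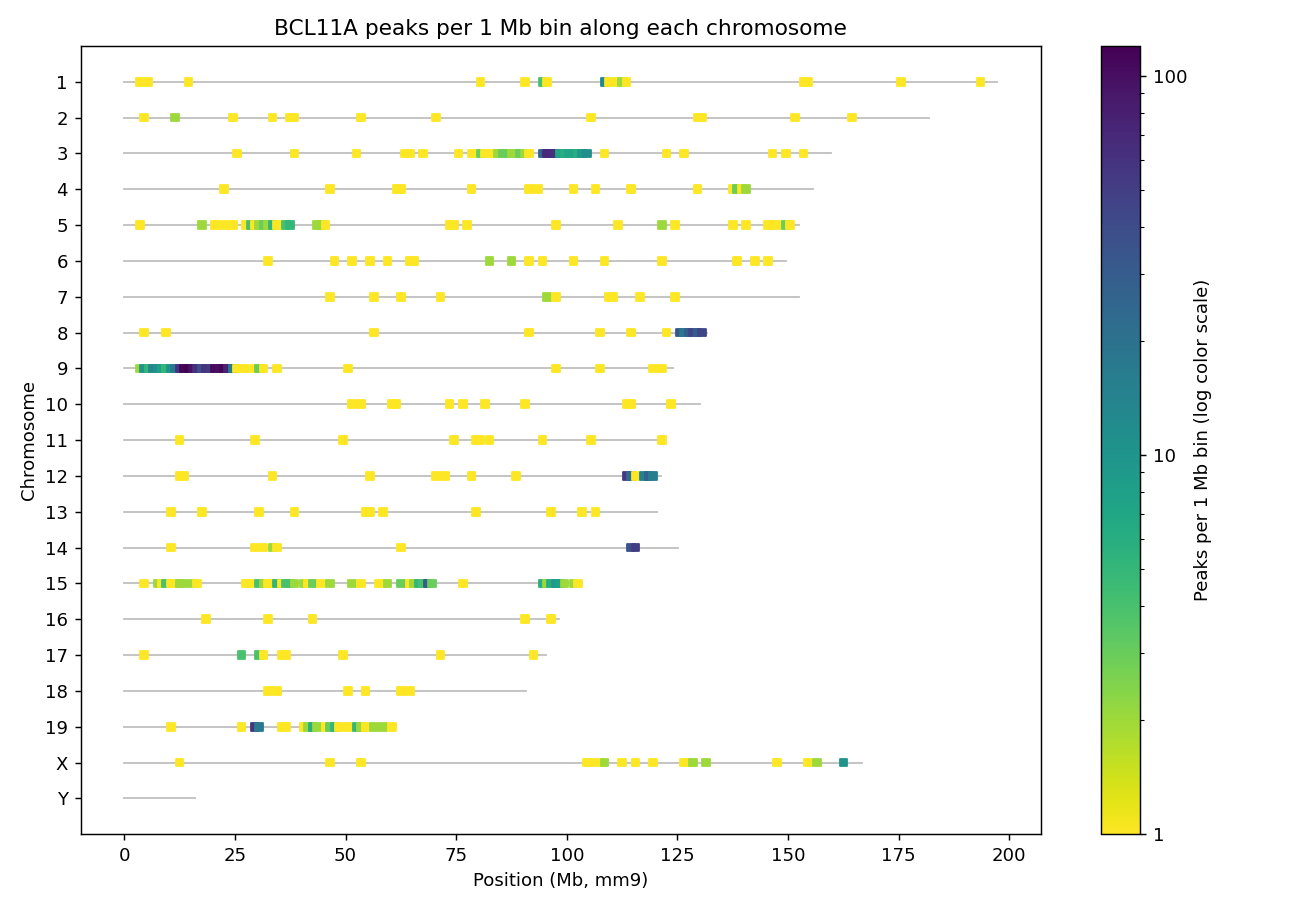
Number of BCL11A peaks in each 1 Mb bin (square, log color scale) along each chromosome (rows, position in Mb of mm9); gray lines are chromosome lengths, and bins without a square hold no peak. Dark bins form blocks on chromosomes 3, 8, 9, 12, 14, 15 and 19, and the densest bin holds 118 peaks.

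Within chromosomes, peaks were concentrated in a few blocks. Of 2665 bins of 1 Mb, 2315 held no peak and 28 held 20 or more. Runs of at least 20 peaks with neighbouring centres at most 250 kb apart formed 10 domains on 7 chromosomes. They held 1782 of the 2370 peaks (75.2%, Wilson interval 73.4 to 76.9) in 27.1 Mb, which is 1.02% of the chromosome length. The density was 65.7 peaks per Mb inside and 0.224 outside, a difference that the choice of dense runs itself ensures. Peaks shuffled uniformly within their chromosomes put a median of 16.0% of peaks in such runs (range 7.89 to 25.5% over 1000 shuffles). The number of runs was not above that in these shuffles, which held a median of 14 (range 7 to 23). Peaks placed uniformly over all chromosomes put 0% there in each of 1000 draws. Without chromosome 9, 59.7% of the remaining peaks lay in 9 domains.

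The longest domain spanned 12.8 Mb of proximal chromosome 9, from 11385633 to 24234281, with 1027 peaks, or 79.9 per Mb. Between 12 and 24 Mb, every 1 Mb bin there held 38 to 118 peaks. Its median score was 61.9 (95% interval 60.6 to 63.4). On chromosome 3, 226 peaks lay between 94496948 and 97760150 (69.3 per Mb, median score 60.6). The highest density was on chromosome 14, with 86 peaks in 0.860 Mb from 114581982 to 115441706 (100.03 per Mb, median score 70.1), and with 0 peaks in the 1 Mb on either side. Chromosome 19 held 73 peaks between 29304902 and 30163269 (85.0 per Mb), and chromosome 15 held 33 between 68617246 and 69050285 (76.2 per Mb). Distal chromosome 12 carried 79 peaks from 113161303 to 114789472 and 57 from 117375345 to 119629840, the latter at 25.3 per Mb.

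Distal chromosome 8 had 3 neighbouring domains and the highest scores. They held 59 peaks from 125093056 to 127320943, 79 from 127714399 to 129176354 and 63 from 129458919 to 130736869, and the last ended 1.00 Mb before the chromosome end. The median scores were 63.1 (95% interval 57.0 to 70.2), 74.0 (66.0 to 92.4) and 77.1 (68.8 to 92.5). Of the 10 highest-scoring peaks, 7 lay on chromosome 8, 2 on chromosome 9 and 1 on chromosome 15, and all 10 lay inside domains. The highest was on chromosome 8 at 125320630 to 125324076, 3447 bp wide with a score of 362.90. It was followed by chromosome 8 at 130017290 to 130019512 with 315.87, chromosome 9 at 20566600 to 20568780 with 270.83, and chromosome 8 at 125278470 to 125280908 with 260.21. The chromosome 15 peak, at 68989895 to 68992074, scored 242.70. The other 5 were chromosome 8 at 130566194 to 130569002 (score 240.52), chromosome 9 at 20681987 to 20684388 (226.83), and chromosome 8 at 127841304 to 127842923 (221.27), 128166496 to 128168443 (204.79) and 128603437 to 128605897 (197.15).

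**Figure D2:**
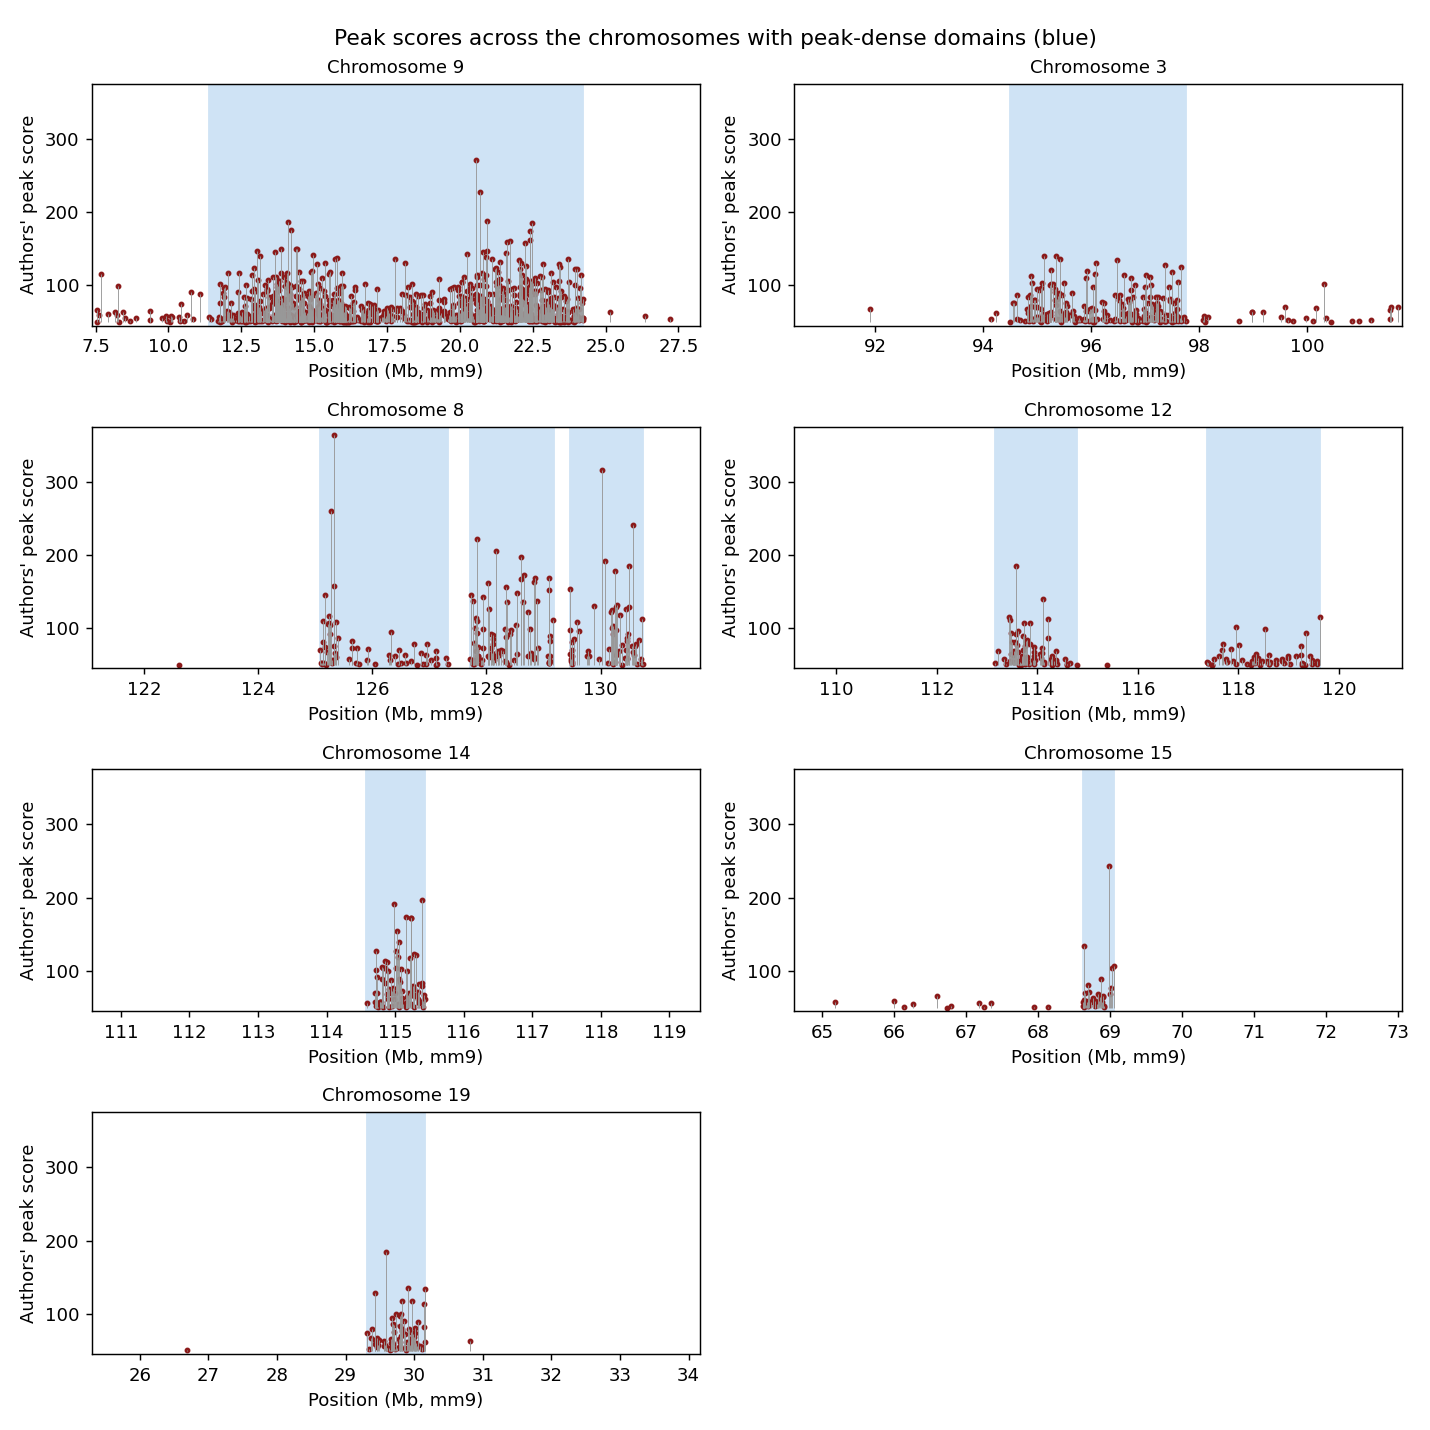
Authors' peak score (vertical axis, no stated unit, floor of 50) against position (Mb, mm9) on the 7 chromosomes with domains; each point is 1 peak and blue bands mark the 10 domains. Peaks outside the bands are sparse, and the highest score, 362.90, is on chromosome 8.

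The 5 densest windows of 100 kb were all on chromosome 9. The first, from 13767362 to 13867361, held 25 peaks with a median score of 70.8 (95% interval 61.2 to 74.7). The window from 22371328 to 22471327 held 20, and those starting at 13910726, 20517565 and 21407041 held 19 each. The window at 20517565 contained the peak with a score of 270.83.

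Peaks lay closer together than random positions on the same chromosomes. Another peak lay within 10 kb of 1490 of 2370 peaks (62.9%, Wilson interval 60.9 to 64.8), against 8.98% in shuffled lists (central 95%, 7.38 to 10.5%), with a two-sided permutation p of 0.002, the smallest that 1000 shuffles can give. The median distance to the nearest peak was 6.30 kb, against 97.3 kb in shuffled lists (p = 0.002, permutation). Much of this gap goes with regional density: after moving each peak by a random offset of up to 1 Mb, 51.7% of peaks (central 95%, 49.96 to 53.3%) had such a neighbour and the median distance was 9.33 kb. Such offsets spread the shorter domains into their flanks, so the remaining gap does not measure closeness within regions. Outside the domains, 70 of 588 peaks (11.9%, Wilson interval 9.53 to 14.8) had such a neighbour, against 0.973% in shuffled lists (p = 0.002, permutation). These shuffles ran over whole chromosomes, while some of the 588 peaks lay in stretches of raised density. The gap therefore does not separate closeness from regional density. Inside the domains, the median distance to the nearest peak was 4.53 kb and did not differ detectably from 4.90 kb for uniform placement within each domain (central 95%, 4.52 to 5.31 kb, permutation p = 0.0619). This placement let peaks overlap, which the listed peaks do not, so it could miss a somewhat closer spacing.

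Clustered peaks scored higher. The 1490 peaks with a neighbour within 10 kb had a median score of 62.6 (95% interval 61.5 to 63.8) and the other 880 had 56.2 (55.9 to 56.9), a difference of 6.37 (5.10 to 7.80, permutation p = 2e-05). The order turned when the score was divided by the peak width, with medians of 0.0762 and 0.0787 per bp (difference -0.00243, 95% interval -0.00345 to -0.000977, permutation p = 0.00046). The score has a floor and most peaks lay close to it, and among such peaks this ratio falls as the width rises. The ratio therefore cannot tell a lower score from a wider peak, and no conclusion is drawn from the turn. Peaks inside domains had a median score of 62.5 (61.5 to 63.6) and a median width of 848 bp (826 to 868), against 55.0 (54.2 to 55.9) and 683 bp (678 to 688) outside. Of the 1782 peaks inside, 228 scored over 100 (12.8%, Wilson interval 11.3 to 14.4), against 10 of 588 outside (1.70%, 0.926 to 3.10). Only 70 of the 1490 clustered peaks lay outside the domains. The comparison of clustered with other peaks therefore overlaps strongly with that of inside with outside. Among the 588 peaks outside, the median score of clustered peaks was 3.72 higher than that of the others (permutation p = 0.00222).

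Across peaks, score and width rose together, with a Spearman rho of 0.63 (95% interval 0.60 to 0.66, permutation p = 2e-05). Outside the domains rho was 0.15 (permutation p = 0.0004). Scores there lay closer to the floor, with 1.70% over 100 against 12.8% inside, and all 15 peaks under 400 bp were outside. Both can lower rho, so the lower value does not show a different relation of score and width. Peaks of 1 list are not independent replicates.

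**Figure D3:**
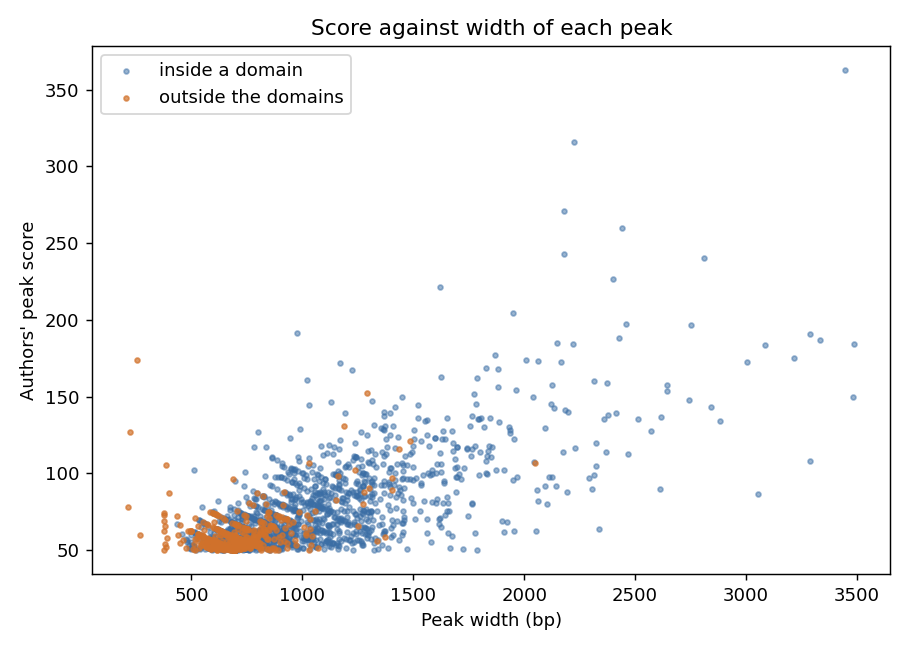
Authors' peak score (vertical axis, no stated unit) against peak width (bp), 1 point per peak, blue for the 1782 peaks inside domains and orange for the 588 outside. Wide, high-scoring peaks are mostly blue, and the 15 peaks under 400 bp at the left are all orange.

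The 588 peaks outside the domains were uneven between chromosomes too, in part with other calls than the whole list. Chromosome 15 held 112 of them (4.89 times the uniform count, adjusted p = 2.11e-42, exact binomial test), chromosome 3 held 94 (2.66 times), chromosome 9 held 78 (2.84 times), chromosome 5 held 58 (1.72 times) and chromosome 19 held 40 (2.94 times). These 5 were above and 12 were below the uniform count. The call turned for chromosome 8 (0.24 times, exact test, adjusted p = 5.96e-06) and chromosome 12 (0.34 times, exact test, adjusted p = 0.000189), which were above over all peaks, and for chromosome 5, which was below. On chromosome 15, 27 of the 112 lay between 95 and 100 Mb, and on chromosome 5, 13 of the 58 lay between 30 and 35 Mb. The 13 chromosomes without a domain that held any peak had 241 peaks among them.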

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

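The alternatives on chromosomes 8 and 9, on the domains, on peaks outside them and on the densest window were chosen after seeing the data. Several tested values kept their direction and passed the threshold but shrank greatly outside the domains: rho fell from 0.63 to 0.15, the chromosome 9 ratio from 9.98 to 2.84 and the share with a neighbour within 10 kb from 62.9% to 11.9%, while the median nearest distance rose from 6.30 to 184 kb. Over all peaks, this score difference turned, to -0.00243 per bp of width in place of 6.37. Because the score has a floor, the value per bp cannot tell a lower score from a wider peak. The cause of the turn was not tested. Among the 1185 highest-scoring peaks the median width was 992 bp and the median score, raised by the choice itself, was 74.5. The domain rule applied to them alone gave 8 domains with 81.7% of these peaks. In this set, 4 chromosomes in place of 6 were above the uniform count. Without chromosome 9, 1265 peaks remained, with medians of 735 bp and 58.3 and 59.7% of them in domains. Outside the domains were 588 peaks with medians of 683 bp and 55.0. Domains held 81.3% of peaks with a gap of 500 kb, 82.3% with a gap of 1 Mb and 79.0% with at least 10 peaks, which gave 17 domains; they held 73.0% of peaks merged within 1 kb. Spacing stayed closer than shuffled under its 7 alternatives, the one with offsets carrying the limit given with its value, and rho stayed positive under its 4. No paired analysis was possible because each group has 1 sample and 1 peak list was used. The alternatives that need mm9 sequence or annotation (assembly gaps, start sites, genomic classes, gene lists, loci, motifs, base composition) were not run. Depth limits cannot be stated, since the list gives no reads.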

Other observations

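Some smaller groups of peaks lay outside the 10 domains. On chromosome X, 10 peaks fell within 59.4 kb, from 162787194 to 162846605, with a highest score of 152.16. On chromosome 1, 12 peaks lay between 108304830 and 108527614, with a highest score of 96.90. Beside the domains of chromosomes 3 and 9 lay long stretches of lower but raised density: 53 peaks over 7.15 Mb from 97760151 to 104910130 on chromosome 3 (7.41 per Mb, median score 54.1) and 64 peaks over 8.20 Mb from 3186081 to 11385632 on chromosome 9 (7.81 per Mb, median score 56.6), against 0.224 per Mb outside domains as a whole. On the other side of the chromosome 3 domain, 13 peaks lay between 85 and 90 Mb (2.6 per Mb). Chromosome 15 held raised densities in several places, with 13 peaks over 4.34 Mb before its domain (3.00 per Mb), 2.6 per Mb between 30 and 35 Mb and 5.4 per Mb between 95 and 100 Mb.

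Some of the shortest peaks had high scores. The 15 peaks shorter than 400 bp were singled out after seeing the data, so no p-value is given for them. They lay on 11 chromosomes, 0 of them in a domain, and had a median score of 69.2 (95% interval 58.2 to 87.4). The median was 52.6 (52.3 to 52.9) for the 713 peaks of at least 600 and under 700 bp, and 55.0 (54.2 to 55.9) for all peaks outside the domains. Over the whole list it was 59.4, which lies within the interval of the 15 peaks. The highest were a peak of 254 bp on chromosome 14 at 33674916 to 33675169, with a score of 173.89, and one of 221 bp on chromosome 10 at 113964532 to 113964752, with 127.19.

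The concentration of 75.2% of peaks in 10 domains was weighed against 3 explanations; all of these tests were chosen only after the domains had been seen. Uniform placement is argued against, since no shuffle within chromosomes put more than 25.5% of peaks in such runs. Splitting of broad regions into short peaks is argued against only for gaps of at most 1 kb. Domains still held 73.0% (Wilson interval 71.1 to 74.8) after peaks with edges within 1 kb were merged. Splitting with wider gaps was not tested, and the median spacing of centres in the domains ran from 6.96 to 31.7 kb. A higher DNA copy number in these cells, or another regional gain in read coverage that the control did not remove, cannot be told apart from a truly denser BCL11A occupancy of these stretches. Scores inside were 7.53 higher than outside (95% interval 6.16 to 8.78), which either could give. The coverage of the BirA-only and input samples, which bears on this question, was not used here.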
